A study of Mus musculus with 6 samples.

How the data were processed

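The data are 6 mouse RNA-seq libraries of MC3T3-E1 cells, 3 per group, with and without RAW264.7 supernatant on nano/microstructured PEEK. Per the labels' protocols, poly(A) RNA was selected with oligo(dT) beads and fragmented, second strands were made with dUTP and digested, adapters carried unique molecular identifiers, and paired-end reads were made on a NovaSeq instrument. The titles call 2 of the 3 libraries of each group biological replicates; nothing else in the labels says whether the libraries came from separate cultures, so p-values measure the spread between these libraries. Libraries were grouped by the treatment label, and replicate numbers were taken from the library names.

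The deposited table gave for each gene a raw count and an FPKM value per library, per the file headers. Cutadapt 1.9 and HISAT2 2.2.1 are named in the submitters' processing notes. The genome build, the annotation, the counting tool, its use of strand, and the treatment of molecular identifiers and of reads with several matches are not given in the sources used here. Of the 30071 gene IDs, 28415 occur in GENCODE M21 (GRCm38), but only 2.2% of those share its start position, so coordinates are those of the deposited table and none were taken from the reference. Gene symbols are those of the table. If reads of near-identical copies were discarded, split or counted more than once, values of multi-copy families and of genes with processed pseudogenes would move. The total count per library was 74927500 to 82803173; intervals or limits from counts cover counting error only. No pair of libraries held identical values, and the chi-square per gene between libraries was 25.6 to 112, far above sampling noise. No library was thus taken as a copy of another, and each was counted as 1 replicate. This cannot show that they came from separate cultures. The lowest values were between replicates 2 and 3 of each group, 25.6 on PEEK alone and 35.15 with supernatant.

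The planned test depended on the unit, and since counts were present edgeR 4.0.16 in R 4.3.3 was used on the deposited counts: TMM normalization, filterByExpr (minimum count 10, minimum total 15), which kept 18177 genes, quasi-likelihood fits with group as the only term, and Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 fold change was its size divided by the square root of the F statistic. CPM values use the TMM-scaled library sizes. Gene lists with 5 or more tested members were tested by camera (limma 3.58.1) with a preset correlation of 0.01, and beside it with an estimated correlation and with fry, with adjustment over the 27 lists. Terms of the table's Gene Ontology and KEGG columns with 10 to 500 tested members were tested by a one-sided Fisher's exact test against tested genes with an annotation. List medians per library used log2 CPM with a prior count of 2.

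Genes were named by a rule set before the data were examined: the 8 rising and 8 falling genes of largest change past the threshold whose groups did not overlap and whose higher mean reached 2 FPKM, leaving out unnamed models, pseudogenes and ribosomal protein genes, or, if none passed, the 8 of smallest p; 12 fixed genes of osteoblasts and their signals; and from each list up to 4 members past the threshold or, if none, up to 2 of smallest p. For the lysosome list, 1 of the members so chosen is not reported here. The lists and the alternatives were also set then. The lists were: osteoblast differentiation and bone matrix, collagen and matrix assembly, matrix proteases and inhibitors, inflammatory cytokine and NF-kB response, interferon response, cell cycle, Wnt signalling, BMP and TGF-beta signalling, osteoblast signals to osteoclasts, angiogenic factors, hypoxia and glycolysis, oxidative phosphorylation, Nrf2 and oxidative stress, ER stress and integrated stress response, cholesterol biosynthesis, adhesion and cytoskeleton, p53 targets, immediate early genes, lysosome and autophagy, mitochondrially encoded transcripts, replication-dependent histones, and markers of macrophages, osteoclasts, adipocytes, chondrocytes, endothelium and smooth muscle.

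Alternatives were DESeq2 1.42.0, edgeR with DESeq2 size factors, no low-count filter, limma on log2(FPKM + 1) over genes of at least 1 FPKM in 3 libraries with its own choices of pseudocount (0.1, 0.5), filter (none, 5 FPKM), scaling, trend and robust fit, the replicate number as a block, leaving out each library, an adjusted p under 0.01, and terms of 20 to 300 members. Replicate numbers occur in both groups, but deviations from the group means correlated at −0.03, −0.01 and 0.02 between same-numbered libraries, so the numbers were not treated as pairs.

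The tests were checked on simulated counts drawn for the supernatant comparison from the means, library sizes and dispersions of the real libraries, with 200 genes changed. The changed genes were drawn from those above a minimum level, and a further list of slightly raised genes was left out of the scoring. Each gene was drawn independently, so the rates below do not cover shifts shared by many genes of a library. An adjusted p threshold also admits larger unadjusted p where many genes change. The rates therefore need not hold for the real comparison, where edgeR called 3 genes. With edgeR, run on 17629 simulated genes, 40% of genes changed 1.5-fold, 68% of those changed 2-fold, 95.9% at 4-fold and 98% at 8-fold were recovered, with 13 false calls among 163. DESeq2, run on 18177 genes, recovered 60, 86, 96 and 100% and made 62 false calls among 234. Limma on simulated FPKM, run on 12061 genes, recovered 31.8, 66, 100 and 100%, with 8 false calls among 140.

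For the retroviral search, 4 segments of murine leukaemia virus Gag, polymerase and envelope protein, written from general knowledge of the Moloney strain, were searched with tblastn 2.17.0 (E-value at most 1e-05) against GENCODE M21 transcripts, and matches of at least 50 amino acids were kept. Of the tested genes 452 have no transcript in that release and were not searched. Figures were drawn with matplotlib 3.10.9.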

Results

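Poly(A)-selected RNA was sequenced from MC3T3-E1 cells, a mouse pre-osteoblast line, cultured on polyetheretherketone (PEEK), a polymer used for bone implants, whose surface carried nano- and microscale structure. The cells were grown on this surface alone (3 libraries) or with supernatant from RAW264.7 cells, a mouse macrophage line (3 libraries). What the RAW264.7 cells themselves were grown on is not given in the sources used here. Total counts were 76895736, 82803173 and 79242264 in replicates 1, 2 and 3 on PEEK alone and 76978215, 74927500 and 80861720 in replicates 1, 2 and 3 with supernatant. The table listed 30071 genes, of which 18177 had enough counts to be tested. Values below are normalized CPM (counts scaled to library size), as mean ± SD over 3 libraries unless stated, and log2 fold changes are with supernatant minus without.

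The comparison asked which transcripts of the osteoblast line differed when macrophage supernatant was present. Col6a3, which encodes a chain of the microfibril-forming collagen VI, fell from 20.3 ± 1.07 CPM on PEEK alone to 5.51 ± 1.05 CPM with supernatant (n = 3 each). Its log2 fold change was −1.88 (SE 0.16, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0167), and all 3 libraries with supernatant lay below all 3 without. A pair of loci without a gene name rose: Gm42427 from 0.564 ± 0.0454 to 35.5 ± 21.8 CPM (log2 fold change 5.97, SE 0.47, adjusted p = 0.0167) and Gm48274 from 0.0548 ± 0.00857 to 2.40 ± 1.27 CPM (log2 fold change 5.42, SE 0.51, adjusted p = 0.0249). These were the only 3 genes past the threshold with edgeR, all 3 of them changed more than 2-fold, and 1627 genes had an unadjusted p under 0.05. The loci Gm42427 and Gm48274 lie outside the naming rule and were chosen after their values were seen.

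Col6a3 (ENSMUSG00000048126) is on chromosome 1 from 90693645 to 90771693, minus strand, in the coordinates of the deposited table, whose genome build is not given in the sources used here. Gm42427 (ENSMUSG00000105263) is on chromosome 5 from 44295322 to 44300613 and Gm48274 (ENSMUSG00000111083) on chromosome 10 from 50300182 to 50300436, both on the plus strand. The table gives both the transcript type TEC, an unclassified type, and all values are for whole genes, with no separation of exons, introns or UTRs. In a translated search, the transcript of Gm42427 matched a segment of the murine leukaemia virus polymerase at 97.3% identity over 338 amino acids. That of Gm48274 matched the same protein at 100% identity over 84 amino acids, on the strand opposite to the gene. Such sequence has near-identical copies elsewhere in the mouse genome, and how reads with several matches, or reads of either strand, were counted is not given in the sources used here, so the count of a single such locus is uncertain.

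DESeq2 called 294 genes on the same counts, 168 higher and 126 lower with supernatant, and these included all 3 above. None of Col6a3, Gm42427 and Gm48274 passed with edgeR when replicate 1, 2 or 3 of PEEK alone was left out, where 1, 0 and 0 genes were called and 2132, 1068 and 1020 had an unadjusted p under 0.05; without replicates 1, 2 and 3 with supernatant 199, 5 and 3 genes were called, and all of these 3 loci but Gm48274 (without replicate 3) were among them.

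**Figure D1:**
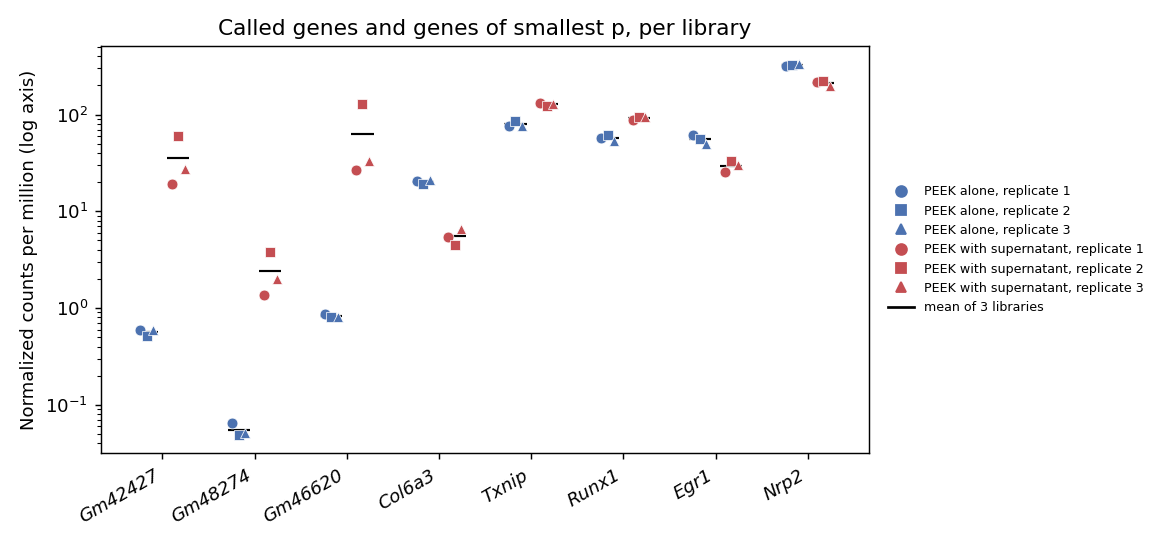
Normalized CPM (log axis) of the 3 genes past the edgeR threshold (Gm42427, Gm48274 and Col6a3) and of 5 genes whose groups do not overlap but whose adjusted p was 0.0562. Each point is a library, shaped by its replicate number, and bars are means of 3 libraries; Col6a3 goes from 20.3 to 5.51 and Gm42427 from 0.564 to 35.5.

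No gene that met the level and naming requirements of the rule passed the edgeR threshold in either direction, so the 8 of smallest p on each side are given as values. DESeq2 called all 16 of them (adjusted p 8.09e-09 to 3.35e-04), and edgeR without replicate 1 with supernatant called 14, all but Steap3 and Arrdc3 (adjusted p 0.0234 to 0.0576). Since the genes were chosen by p on the same counts, these calls are not independent support. Of 21 or 22 alternatives per gene, between 1 (Steap3 and Arrdc3) and 4 (Txnip) called it. When each library was left out in turn, the highest edgeR adjusted p ranged from 0.295 (Egr1) to 0.621 (Mast4). On the higher side, Txnip, a thioredoxin-binding regulator of glucose uptake, was at 79.2 ± 5.68 CPM without and 128 ± 3.57 CPM with supernatant (log2 fold change 0.69, SE 0.08, edgeR adjusted p = 0.0562). Runx1, a transcription factor related to Runx2, was at 57.2 ± 4.39 and 91.9 ± 4.11 CPM (0.68, SE 0.08), Tns3, which encodes an adhesion-site tensin, at 138 ± 11.7 and 218 ± 4.85 CPM (0.66, SE 0.08), and Snx18, an endosomal sorting nexin, at 108 ± 7.42 and 168 ± 7.69 CPM (0.64, SE 0.08), each with the same adjusted p. Pxdc1, Ttc39b, Mast4 and Nlrp2 followed, with log2 fold changes of 0.87, 0.51, 0.44 and 0.76 and adjusted p of 0.101 to 0.127. On the lower side stood Ppl, which encodes the cell junction protein periplakin (21.5 ± 2.68 and 10.6 ± 0.756 CPM, log2 fold change −1.02), the semaphorin and VEGF co-receptor Nrp2 (323 ± 6.85 and 213 ± 13.4 CPM, −0.60) and the immediate early transcription factor Egr1 (55.9 ± 5.61 and 29.5 ± 3.63 CPM, −0.92), with an adjusted p of 0.0562 each. Adgrl4, Selenow, Steap3, Plin4 and Arrdc3 had log2 fold changes of −0.55, −0.69, −0.84, −1.30 and −0.85 and adjusted p of 0.0793 to 0.151. Over all tested genes, 1424 had every library with supernatant above every library without, and 1337 the opposite, together 15.2% of genes against the 10% that chance gives on average for 3 against 3. Genes vary together across libraries, so a single grouping can depart from 10% without any effect. The share was not computed for other groupings of the libraries.

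Genes of osteoblast differentiation and bone turnover that were fixed in advance did not pass the threshold. Alpl, the alkaline phosphatase of mineralizing cells, was at 24.4 ± 7.17 CPM on PEEK alone and 43.0 ± 35.3 CPM with supernatant (log2 fold change 0.82, SE 0.50, edgeR adjusted p = 0.680). The 3 libraries with supernatant held 83.7, 24.98 and 20.4 CPM of Alpl in replicates 1, 2 and 3, and without replicate 1 the log2 fold change was −0.09. Sp7 and Runx2, transcription factors needed to form osteoblasts, were at 13.8 ± 1.33 and 17.1 ± 11.4 CPM and at 149 ± 15.2 and 178 ± 48.9 CPM (adjusted p = 0.860 and 0.720). Replicate 1 with supernatant was the highest of the 6 libraries for both, at 30.3 CPM for Sp7 and 234.7 CPM for Runx2. Spp1, which encodes osteopontin, was at 354 ± 20.5 and 322 ± 117 CPM (adjusted p = 0.906), with the lowest value, 189.0 CPM, in the same library. The collagen gene Col1a1 (21.6 ± 1.82 and 16.8 ± 5.88 CPM), the sialoprotein gene Ibsp (1.31 ± 0.526 and 0.827 ± 0.851 CPM) and Tnfrsf11b, which encodes the RANKL decoy receptor osteoprotegerin (23.04 ± 5.64 and 19.0 ± 5.86 CPM), had log2 fold changes of −0.37, −0.66 and −0.28. Without replicate 1 with supernatant they had −0.67, −1.93 and −0.55 (edgeR adjusted p = 0.0686, 0.133 and 0.202). Il6 and Ccl2, an inflammatory cytokine and a monocyte chemokine, were at 4.42 ± 2.39 and 2.70 ± 0.117 CPM and at 150 ± 30.7 and 118 ± 34.2 CPM (adjusted p = 0.620 and 0.694). Bglap, the osteocalcin gene, had 0, 2 and 2 counts on PEEK alone and 17, 0 and 0 counts with supernatant and was not tested; Tnfsf11 and Bmp2 were not analysed here.

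**Figure D2:**
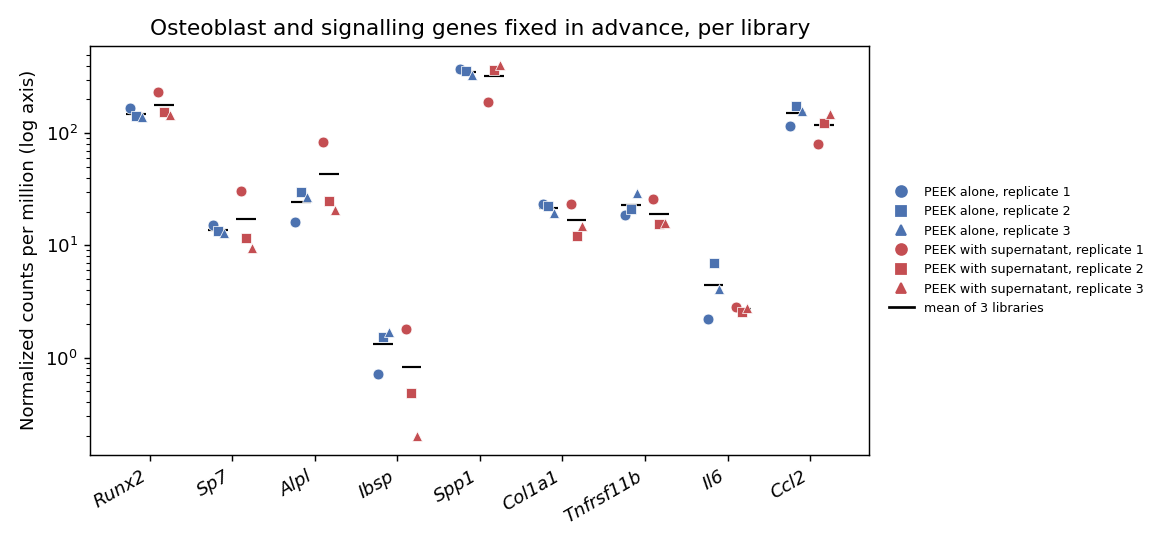
Normalized CPM (log axis) of 9 osteoblast and signalling genes fixed in advance, none of which passed the edgeR threshold. Points are single libraries shaped by replicate number and bars are means of 3 libraries; replicate 1 with supernatant is the highest library for Alpl (83.7), Sp7 (30.3) and Runx2 (234.7) and the lowest for Spp1 (189.0).

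All 27 gene lists fixed in advance were compared with the other genes by camera. With a preset correlation of 0.01 between genes, 2 lists were called higher and 6 lower with supernatant. None of the 8 was called by camera with an estimated correlation, where the smallest adjusted p of any list was 0.779 and the smallest unadjusted p 0.123. The fry test called none in a single direction (smallest adjusted p = 0.519). Only 1 member of any list, Col6a3, passed the edgeR threshold over all genes. Under the preset, leaving out replicate 2 of PEEK alone ended the calls of the interferon (adjusted p = 0.693), lysosome (0.167) and cholesterol lists (0.327), leaving out replicate 1 with supernatant those of oxidative phosphorylation (0.239) and cholesterol (0.651), and leaving out replicate 2 with supernatant those of ER stress (0.137) and cholesterol (0.1303).

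The list of collagen and matrix assembly genes shifted lower under the preset (31 members tested, median log2 fold change −0.19, adjusted p = 1.09e-04), with an adjusted p = 0.779 with an estimated correlation. Its called member was Col6a3; adjusted over the list alone, 3 members fell and 1 rose. The list's median deviation from the control mean was 0.00 in replicate 1 with supernatant and −0.32 and −0.23 in replicates 2 and 3. Its median log2 fold change was −0.09 without replicate 2 with supernatant. Genes of oxidative phosphorylation (40 members, −0.12, adjusted p = 1.39e-05) and mitochondrially encoded transcripts (13 members, −0.24, adjusted p = 1.56e-05) were called lower under the preset, each with an adjusted p = 0.779 with an estimated correlation. The median deviation of the oxidative phosphorylation list was −0.30 in replicate 1 with supernatant and −0.11 and 0.01 in replicates 2 and 3, and its median log2 fold change was −0.04 without replicate 1. The mitochondrially encoded list had −0.40, 0.10 and −0.46. Examples were the complex IV genes Cox7a2 (19.7 ± 1.08 and 14.9 ± 1.96 CPM) and Cox7b (30.1 ± 0.521 and 24.2 ± 2.61 CPM), and mt-Co2 and mt-Co3, with log2 fold changes of −0.41 and −0.37. Mitochondrial transcripts took 3.70, 4.68 and 4.66% of counts on PEEK alone and 3.45, 4.49 and 3.25% with supernatant. The median of the mitochondrially encoded list was −0.44 and −0.13 without replicates 2 and 3 with supernatant and −0.14 without replicate 3 of PEEK alone. No member of these lists passed adjusted over all genes or adjusted over the list alone. Camera did not match genes on length. Over all tested genes the log2 fold change had a Spearman rho of 0.082 with the gene length implied by counts and FPKM. Against random lists matched on expression and length, replicate 1 with supernatant had the oxidative phosphorylation list at percentile 0.6 and the mitochondrially encoded list at 91.5. Whether length enters the group shifts was not tested.

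Interferon response genes were called lower (46 members, median log2 fold change −0.45, adjusted p = 1.35e-05), with an adjusted p = 0.779 with an estimated correlation and 0 members past the threshold over all genes or adjusted over the list alone. Their spread within the controls was wide: the list's median deviation was −0.99, 0.78 and 0.23 in replicates 1, 2 and 3 on PEEK alone and −0.49, −0.16 and −0.15 with supernatant. Mx1, an antiviral GTPase, was at 1.21 ± 0.792 and 0.214 ± 0.0343 CPM, and the transcription factor gene Irf1 at 94.3 ± 14.2 and 69.2 ± 2.81 CPM (edgeR adjusted p = 0.305 and 0.308). Lysosome and autophagy genes (26 members, −0.13, adjusted p = 0.00291) and cholesterol biosynthesis genes (23 members, −0.14, adjusted p = 0.0199) were also called lower under the preset. With an estimated correlation their adjusted p = 0.779 and adjusted p = 0.819. Their median deviations in replicates 1, 2 and 3 with supernatant were −0.15, −0.14 and −0.09 for the lysosome list and −0.24, −0.14 and 0.04 for the cholesterol list. The proton pump gene Atp6v0d1 had a log2 fold change of −0.21, and Mvk and Hmgcs1, early enzymes of sterol synthesis, −0.34 and −0.36.

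The cell cycle list was called higher (40 members, median log2 fold change 0.21, adjusted p = 3.17e-09), with an adjusted p = 0.779 with an estimated correlation. The replication genes Cdc6 (31.6 ± 2.58 and 41.5 ± 5.21 CPM) and Mcm7 (242 ± 7.08 and 282 ± 20.3 CPM) had the smallest p, with edgeR adjusted p = 0.382 and 0.488, and no member passed adjusted over the list alone. Its median deviation was −0.05 in replicate 1 with supernatant and 0.29 and 0.40 in replicates 2 and 3. Its median log2 fold change was 0.34 without replicate 1 and 0.11 without replicate 3 with supernatant, and 0.14 without replicate 2 of PEEK alone. Genes of ER stress and the integrated stress response were called higher as well (31 members, 0.12, adjusted p = 0.00146, and adjusted p = 0.779 with an estimated correlation), with −0.03 in replicate 1 with supernatant and 0.21 in both other replicates. The ER chaperone gene Hyou1 and the lipoprotein receptor gene Vldlr had log2 fold changes of 0.27 and 0.26.

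**Figure D3:**
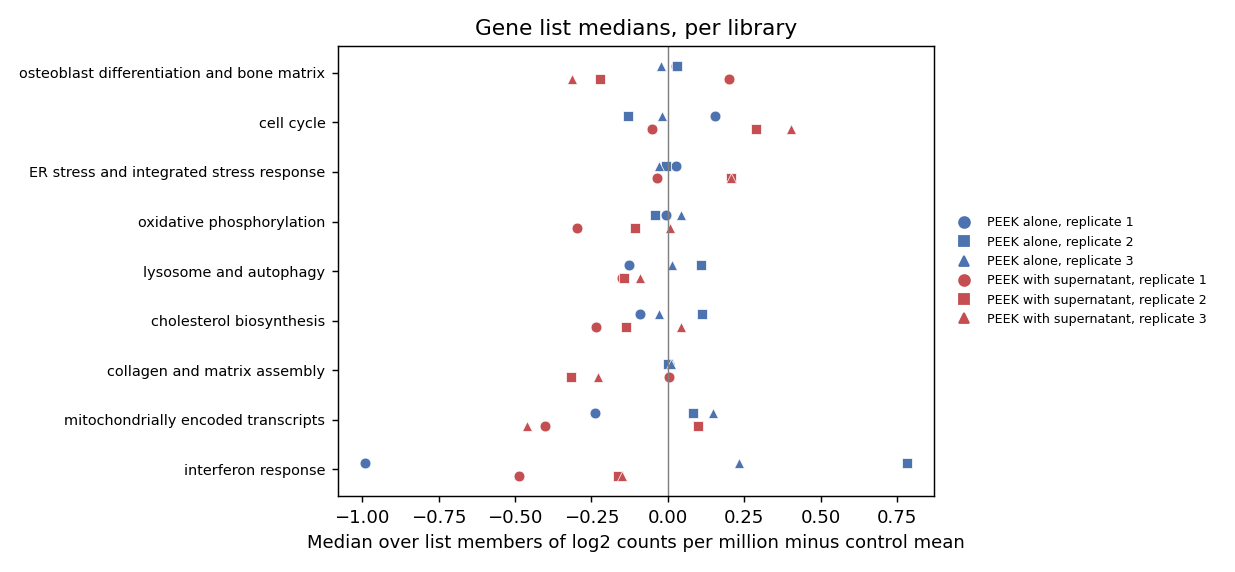
Median over list members of the log2 CPM minus the control mean, for the 8 lists called by camera with the preset correlation and for the osteoblast list. Each point is a library, shaped by its replicate number; for the cell cycle list replicates 2 and 3 with supernatant lie at 0.29 and 0.40 and replicate 1 at −0.05, among the controls.

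The osteoblast differentiation and bone matrix list did not pass (22 members, median log2 fold change −0.15, camera adjusted p = 0.0609), and its median deviation with supernatant was 0.20, −0.22 and −0.31 in replicates 1, 2 and 3. It was called lower under the preset without replicate 1 with supernatant (median log2 fold change −0.30, camera adjusted p = 3.44e-04, and adjusted p = 0.189 with an estimated correlation). It was also called lower without replicate 1 of PEEK alone (−0.14, adjusted p = 0.0464, and adjusted p = 0.877 with an estimated correlation). Enpp1, a pyrophosphate-generating enzyme that limits mineralization, was at 1.84 ± 0.374 and 0.625 ± 0.218 CPM and was the 1 member past the threshold adjusted over the list alone, against 0 over all genes. Phex, an endopeptidase gene of phosphate balance, was at 45.0 ± 4.94 and 35.3 ± 2.61 CPM. For 6 lists, fry's test for changes in either direction passed, while its test for a shift one way passed for none: angiogenic factors (adjusted p = 9.01e-04), osteoclast markers (0.00567), immediate early genes (0.00622), collagen and matrix assembly (0.0084), adipocyte markers (0.0126) and matrix proteases and inhibitors (0.0457). This test does not compare a list with the other genes. Of all 18177 tested genes, 1627 had an edgeR unadjusted p under 0.05, against the 909 that chance gives on average. In these 6 lists the share ran from 1 of 5 osteoclast markers to 14 of 31 collagen and matrix assembly genes. Among angiogenic factors 1 member rose and 5 fell when adjusted over the list alone, led by the receptors Nrp2 and Nrp1, the latter at 35.0 ± 0.446 and 52.6 ± 8.29 CPM (log2 fold change 0.59). Adjusted over the list alone, 2 immediate early genes rose and 2 fell; Egr1 and Egr2 had the smallest p, with Egr2 at 3.45 ± 0.706 and 1.33 ± 0.329 CPM. Of matrix proteases and inhibitors 3 rose and 1 fell on that basis: the stromelysin gene Mmp3 was at 1.74 ± 0.923 and 0.363 ± 0.122 CPM and the inhibitor gene Timp3 at 778 ± 26.3 and 1103 ± 221 CPM. None of these members other than Col6a3 passed over all genes.

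Inflammatory cytokine and NF-kB genes did not shift as a list (35 members, median log2 fold change −0.02, camera adjusted p = 0.688). Without replicate 1 of PEEK alone the list was called lower under the preset (median −0.06, adjusted p = 0.0163), with an adjusted p = 0.877 with an estimated correlation. Adjusted over the list alone 2 of them fell, the chemokine genes Cx3cl1 (617 ± 39.5 and 446 ± 38.6 CPM) and Cxcl1 (214 ± 24.0 and 158 ± 12.9 CPM), whose edgeR adjusted p over all genes were 0.254 and 0.287. Of the Nrf2 list (29 members, −0.02, adjusted p = 0.561), 1 member fell adjusted over the list alone; the glutathione transferase gene Gstm1 was at 109 ± 5.55 and 83.7 ± 5.46 CPM and the peroxidase gene Gpx1 at 61.1 ± 7.54 and 37.6 ± 13.7 CPM. The Nrf2 list was called higher without replicate 1 with supernatant (median 0.10, adjusted p = 0.0205, and adjusted p = 0.664 with an estimated correlation). It was called lower without replicate 3 with supernatant (−0.15, adjusted p = 0.00417, and adjusted p = 0.706 with an estimated correlation). The list of osteoblast signals to osteoclasts had 1 member that rose adjusted over the list alone (13 members, −0.10, camera adjusted p = 0.733), with Efnb2 at 18.9 ± 3.27 and 27.7 ± 1.75 CPM and Il34 at 21.7 ± 3.82 and 17.1 ± 1.40 CPM. In the lists of Wnt signalling (28 members, 0.12, adjusted p = 0.363), BMP and TGF-beta signalling (29 members, 0.04, 0.480), hypoxia and glycolysis (32 members, 0.01, 0.363), adhesion and cytoskeleton (35 members, 0.06, 0.101), p53 targets (18 members, 0.03, 0.966) and replication-dependent histones (11 members, −0.05, 0.697) no member passed by either adjustment. The members of smallest p were Lrp5 and Rspo2, with log2 fold changes of 0.27 and 0.68, Grem1 and Smad9 (−0.47 and 0.31), Pfkfb3 and Slc2a1 (−0.80 and −0.27), Lats2 and Srf (0.27 and 0.23), Perp and Ccng1 (−1.53 and −0.32), and H1f4 and H1f2 (1.00 and −0.29). Without replicate 1 of PEEK alone H1f4 was at 1.76 and H1f2 at −0.15, without replicate 3 with supernatant H1f2 was at −0.13, and without replicate 1 with supernatant Ccng1 was at −0.21. Replicate 1 with supernatant had a median deviation of 0.41 for the Wnt list, against −0.05 in each of the other replicates with supernatant. The test's direction differed in sign from the median or the mean for the lists of proteases, inflammation, hypoxia, Nrf2, osteoclast, adipocyte, chondrocyte and smooth muscle markers and histones, none of them called.

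The fixed lists also held markers of other cell types, among them the macrophages that made the supernatant. Of 28 macrophage markers 21 were in the table. Ctss and Rac2 had 0 counts in all 6 libraries, which at these totals allows up to 3 counts per library, and Ptprc, the pan-leukocyte gene, had 4 counts in a single library with supernatant. The highest markers were Cd14 and Cd68, at 4.56 and 1.95 FPKM on PEEK alone and 4.08 and 1.45 FPKM with supernatant. The lysozyme gene Lyz2 was at 0.383 and 0.327 FPKM. As a list, the 9 tested macrophage markers did not shift (median log2 fold change 0.11, camera adjusted p = 0.480), with Lcp1 and Fcgr3 of smallest p at 1.33 ± 0.332 and 2.19 ± 0.421 CPM and at 0.257 ± 0.0787 and 0.504 ± 0.0602 CPM. Osteoclast (5 tested), adipocyte (6), chondrocyte (8), endothelial (5) and smooth muscle or myogenic markers (8) had camera adjusted p of 0.480, 0.688, 0.688, 0.688 and 0.966. Adjusted over the list alone 1 member fell in each of the osteoclast, adipocyte and smooth muscle lists. Their members of smallest p were Nfatc1 (42.8 ± 4.55 and 31.6 ± 0.836 CPM) and Oscar, Plin4 and Cebpa, Sox5 and Sox6, Vwf and Flt1, and Cspg4 (20.3 ± 9.61 and 8.92 ± 2.15 CPM) and Cnn1. Chondrocyte markers had a median deviation of 0.66 in replicate 1 with supernatant and of −0.48 and −0.65 in replicates 2 and 3.

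No annotated term passed a one-sided Fisher's exact test among the edgeR calls, of which Col6a3 alone was annotated in Gene Ontology or KEGG; the DESeq2 calls gave 13 terms. Pairwise Pearson correlations of log2(FPKM + 1) across genes, which are not independent replicates, were 0.979 to 0.993. The pairs of replicates 2 and 3 within each group were the closest, at 0.991 on PEEK alone and 0.993 with supernatant. Replicate 1 with supernatant correlated at 0.980 on average with the other libraries of its group and at 0.982 with the controls. On the first principal component of log2 CPM (29.4% of variance) replicates 2 and 3 with supernatant lay at 41.7 and 53.2, and replicate 1 at −23.6, within the range of −31.0 to −11.1 of the controls. Replicate 1 of PEEK alone lay at 59.5 on the third component (19.1% of variance), where the other libraries lay between −18.5 and 3.78. It correlated at 0.984 on average with its own group and with the other.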

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

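Robust edgeR estimation, limma with the block, the estimated correlation without 1 library and the term tests on DESeq2 or reduced edgeR calls were chosen after seeing the data. The causes of the differences below were not tested. The count of 3 genes (2 higher, 1 lower; 3 over 2-fold) was also 3 with DESeq2 size factors, robust edgeR and limma on log2(FPKM + 1), plain, median-ratio scaled or robust, but limma shared only 1 of the 3 genes in these fits. DESeq2 called 294 genes (102 over 2-fold). Limma called 7 (6 over 2-fold; 6 higher, 1 lower) with pseudocount 0.5, 3 higher and 0 lower with pseudocount 0.1, 11 (7 higher, 4 lower) with a filter at 5 FPKM, 5 (5 over 2-fold; 5 higher, 0 lower) rescaled to TPM and 4 (2 higher, 2 lower) without trend. Counts were 0, also over 2-fold, for edgeR with no low-count filter (1903 at an unadjusted p under 0.05), limma with no filter (2221) and limma quantile normalized (1359), and 0 at adjusted p under 0.01 (1627).

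With the replicate block edgeR called 0 genes and 0 over 2-fold (1330 unadjusted), limma 0 and 0 (1112), and camera 9 lists, the added one being the osteoblast list (adjusted p = 0.0397). Same-numbered libraries had correlations of deviations of −0.03, −0.01 and 0.02, and not every library correlated best with its own number.

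Leaving out 1 library gave 0 to 199 genes, 0 to 85 over 2-fold and 5 to 10 lists. Gene counts were 1, 0 and 0 without replicates 1, 2 and 3 of PEEK alone (unadjusted 2132, 1068 and 1020), and 199, 5 and 3 without those with supernatant; 5 lists were called without replicate 2 of PEEK alone. Without supernatant replicate 1 the signs of Sp7 (range −0.37 to 0.60), Alpl (−0.092 to 1.15) and Spp1 (−0.34 to 0.15) reversed. Over all alternatives Col6a3 stayed between −2.04 and −0.85 (adjusted p 8.61e-25 to 0.339), Gm42427 between 2.59 and 6.29 (1.75e-27 to 0.392) and Gm48274 between 2.92 and 5.71 (7.20e-16 to 0.339).

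Camera with an estimated correlation called 0 lists, with all libraries or without any 1 of them, and fry directional 0. Terms passing were 0 for edgeR, also at 20 to 300 members, 13 for DESeq2 calls (12 at 20 to 300) and 16 for edgeR without supernatant replicate 1. Col6a3 was the only annotated edgeR call, too few for a term to pass, so that 0 decides nothing. Leave-one-out medians were −0.746 to −0.064 for interferon response (call lost without replicate 2 of PEEK alone), −0.189 to −0.040 for oxidative phosphorylation (lost without supernatant replicate 1), −0.210 to −0.057 for cholesterol biosynthesis (lost without replicate 2 of PEEK alone or supernatant replicate 1 or 2), 0.087 to 0.180 for ER stress (lost without supernatant replicate 2) and −0.166 to −0.070 for lysosome (lost without replicate 2 of PEEK alone), and, with the call kept, 0.113 to 0.341 for cell cycle, −0.280 to −0.094 for collagen and −0.435 to −0.134 for mitochondrially encoded transcripts; the mitochondrially encoded list, at −0.012, lost its call under quantile normalization. Of the single-gene and single-list values, 1117 kept direction and their call or lack of one, 37 gained a call, 26 lost one and 0 reversed. Leaving out libraries, these counts were 473, 17, 17 and 3. Only 3 genes and 8 lists had a call to lose. Over all alternatives, those without 1 library included, Col6a3 was called in 7 of 21, Gm42427 in 9 of 21 and Gm48274 in 13 of 22. Lists were not tested with DESeq2.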

Other observations

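The term tests on DESeq2 calls and on edgeR calls without supernatant replicate 1, and all tests below except 3 (direction of the genes in that library, its length trend, and pluripotency genes), were chosen after the result was seen. Among the 126 genes DESeq2 called lower with supernatant, 11 of 168 annotated genes of collagen-containing extracellular matrix were found where 1.12 would be by chance (Fisher's exact test, Benjamini-Hochberg adjusted p = 2.89e-05), among them Col6a3, Col11a1, Col15a1, Ogn and Omd. The TNF signalling pathway had 7 of 95 (adjusted p = 0.02), including the chemokine genes Cx3cl1, Cxcl1 and Cxcl10 and the transcription factor gene Irf1, but 2 of 93 among the edgeR calls without supernatant replicate 1 (adjusted p = 1). DESeq2 made 62 false calls among 234 on simulated counts. The edgeR fit without supernatant replicate 1 keeps supernatant replicates 2 and 3, the pair of libraries with the highest Pearson correlation (0.9925). Their small spread makes calls easier, and Fisher's exact test treats genes that vary together as independent. In that fit 7 of 30 collagens conferring tensile strength were called lower (adjusted p = 2.37e-08): Col6a1, Col6a2, Col6a3, Col12a1, Col15a1, Col27a1 and Col4a5. With DESeq2 the term had 3 of 31 and did not pass (adjusted p = 0.348). In supernatant replicate 1 Col4a5 (194.4 CPM) and Col27a1 (7.904 CPM) lay above all controls. Col6a1 (1642 CPM), Col6a2 (684.8 CPM) and Col12a1 (322.6 CPM) lay among the controls there, and only Col6a3 and Col15a1 below all of them. In the edgeR fit without that library, 11 of 338 genes of the DNA damage response, such as Top2a, Exo1 and Mcm10, were called higher (adjusted p = 0.0166). With DESeq2 the DNA damage term had 11 of 341 and did not pass (adjusted p = 0.0509). Some terms of smaller p among genes called higher rested mostly on Pramel genes: negative regulation of cell differentiation had 12 of 35 with DESeq2 (adjusted p = 2.19e-13) and 8 of 34 with edgeR without that library (adjusted p = 1.29e-07). Others held none: mRNA export from nucleus had 9 of 50 with DESeq2 (adjusted p = 3.3e-07), Gm20765 and 8 other genes with Gm names.

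Some loci resembling murine leukaemia virus, 6 of 8 of at least 80% identity apart from Gm43305, lay above all controls in each supernatant library. Besides Gm42427 and Gm48274, Gm46620 had 67, 66 and 64 counts on PEEK alone and 2095, 9509 and 2677 with supernatant. Gm4316 had a log2 fold change of 0.79 (edgeR adjusted p = 0.729), and AI506816 of −0.10. Chd9 had −0.14, but it is a protein-coding gene with 71409 counts over all libraries and a match of 77 amino acids. Its count is for the whole gene and need not follow the matched stretch. Retroviral RNA or virus carried by the RAW264.7 supernatant may account for the loci that rose, but stays open. The median log2 ratio of 3.88 over 4 loci of at least 95% identity comes from Gm42427, Gm48274 and a neighbour of each (Gm42428, 2.54, and Gm48275, 1.87). It thus restates the observation at 2 sites, and Gm43305 elsewhere had only 8 counts. Carried-over RAW264.7 cells are argued against, since the highest rise of a macrophage marker was 0.1337 FPKM against 31.96 FPKM for a retroviral locus. A general activation of retroviral loci stays open. The 37 loci of 30 to 80% identity had a median log2 ratio of 0.06 (quartiles −0.21 and 0.40). They cannot decide it, because they include protein-coding genes such as Nopchap1 (63229 counts over all libraries) and Eci2 (28075), counted as whole genes. Others had few counts, such as Gm48362 with 16 over all libraries. Activation of the closest endogenous loci in the osteoblasts cannot be told apart from carried RNA. All 4 loci of at least 95% identity had counts in the controls, and the table holds no base differences.

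Supernatant replicate 1 stood apart from replicates 2 and 3, with 38 genes 2-fold beyond all other libraries; replicate 1 of PEEK alone came next, with 27. A library without supernatant under a wrong label is argued against by the retroviral loci that rose over 10-fold in replicates 2 and 3. These loci, Gm42427, Gm48274 and Gm46620, lay at least 24.93 times above the control mean in replicate 1. Gm42428 and Gm48275, which were not tested, rose less there: they had 0.139 and 0.101 CPM, against at most 0.0366 and 0.0487 CPM in the controls. The test written beforehand did not decide about the label. Of the 199 genes called without that library, 66.8% moved in the called direction in it, between the bounds of 60 and 75%. Lower depth is argued against by its total of 77.0 (in units of 1000000 counts), within the range of the others, and gene length bias is argued against as the whole cause of its list shifts: of 13 lists in the lowest or highest 2.5% of expression-matched random lists, 12 stayed there when length was matched too, and the mitochondrially encoded list moved from 0.1 to 91.5. A smaller length effect stays open, as does an untested difference between the cultures: the rho of 0.099 across genes, far from the 0.3 predicted for such a bias, met the bound of 0.1 written beforehand, but by less than the SD of 0.054 over the other libraries, a margin required only after the value was seen.

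Gene families of the early embryo were higher in supernatant replicates 2 and 3, with summed Zscan4 counts of 42, 0 and 8 on PEEK alone and 33, 878 and 845 with supernatant. Reads shared among copies of 1 family are argued against as the whole cause. In both replicates 4 families (Zscan4, Usp17l, Pramel and Obox) lay above all other libraries. Tdpoz, Tcstv and Zfp352 did so too by CPM, but had under the 100 counts required in at least 1 of the 2. How reads with several matches were counted is not given, so the part of such reads within each family stays open. The test for embryonic stem cells or embryonic RNA mixed in named 8 pluripotency genes, but only Nanog, Esrrb and Dppa5a were analysed here. Their summed counts were 28 and 48 in supernatant replicates 2 and 3, and 61, 51 and 67 on PEEK alone. Embryonic stem cells were predicted to raise them far above the controls, so for these 3 genes the counts argue against such cells. Embryonic RNA cannot be told apart from a change in the cells, since RNA of the 2-cell stage need not hold these 3. Whether a small share of the cells entered such a state was not tested.

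With 10 splits of the 6 libraries no share under 0.05 can be reached. The real split gave 3 genes and the highest other 8, as many or more in 2 of the 10 splits; for genes over 2-fold the values were 3 and 4, in 2 splits, and for gene lists 8 and 12, in 7 splits. The split with 8 genes set replicate 1 of PEEK alone and supernatant replicates 2 and 3 against the rest. It had 2405 genes at an unadjusted p under 0.05 with edgeR, against 1627 in the real split. It differs from the real split only by an exchange of the replicate 1 libraries. Treatment and differences of replicate 1 are therefore mixed in it, and their shares were not tested.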
